A study of Mus musculus with 12 samples.

How the data were processed

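Epithelial cells were taken from submandibular salivary glands of mouse embryos at day 15 of gestation carrying a K5-Venus transgene, in which a fluorescent protein reports activity of the keratin 5 promoter. Per the labels, cells positive for E-cadherin were sorted by flow cytometry into 4 populations by the receptor tyrosine kinase Kit and by Venus, and total RNA was sequenced as single 50 nt reads. There were 12 libraries, 3 of each population: Kit+ K5+, Kit+ K5-, Kit- K5+ and Kit- K5-. The number of embryos or litters in a library is not given in the sources used here.

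The deposited values were whole-number counts of reads per gene. Per the labels' protocols, reads were mapped to GRCm38 with STAR 2.4.2a and counted with featureCounts, and the submitters' processing notes name featureCounts 1.4.6-p3, Picard 1.129 and FastQC, with the build GRCm38.p3. The annotation release and the strand setting are not given in the sources used here. The tables held 43280 gene symbols, and the counts of the series matrix differed from the single tables in 0 cells. For positions, 39469 symbols matched GENCODE M21 on GRCm38, and positions are from that annotation.

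Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes passing filterByExpr numbered 17030. Libraries were scaled by TMM, and all 12 entered a single quasi-likelihood fit with 1 coefficient per population, leaving 8 residual degrees of freedom. The common biological coefficient of variation was 0.437. The 4 pairwise comparisons and the interaction were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over the genes tested, at 0.05. Adjusted p-values for genes below are from this test. Log2 values carry the standard error implied by the F statistic. CPM are edgeR's cpm values after TMM scaling, given as mean ± SD over 3 libraries.

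The 27 gene lists, 9 of them for other cell types, were written before the data were examined, as were the rule for naming genes and most alternatives. Some lists share genes. Also in another list were 9 of 16 salivary progenitor, 8 of 16 distal end bud, 7 of 20 basal duct and 7 of 18 FGF and ERK feedback genes. Counts of these lists are therefore not separate. Named genes were the gate genes Kit, Krt5 and Cdh1, and up to 8 genes in each direction with the largest fold among those past 0.05 with a mean of 10 CPM in the higher group and no overlap of single libraries, predicted genes left out. From each list came up to 4 members past 0.05 or, failing any, up to 2 with the highest mean, and for the interaction the 10 smallest adjusted p-values. Part of the list members given by the rule are written out, picked after their values were seen, and some genes the rule gives are not reported here. Lists were tested with camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over 135 tests, and again with an estimated correlation. Of 7, 13, 6, 15 and 11 lists called in the 4 pairwise comparisons and the interaction, 0 were called with an estimated correlation.

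Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other filters, thinning to the smallest library, a block on library number, the compared groups alone and leaving out each library. Scaling to 18 genes of epithelial cells in general, leaving out libraries 1 to 4, 5 to 8 or 9 to 12, and thinning together with the block were added after seeing the data. The fit was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes had a mean of 10 CPM or more. Counts were drawn with the dispersion trend, without added spread of single genes or of runs. Recovery in these data is therefore not the power over all genes tested. False calls numbered 3, 6, 10, 7 and 3 in the order below. For K5 in Kit+ cells 13 and 91 of these were recovered (16411 genes tested), for K5 in Kit- cells 31 and 90 (16373), for Kit in K5+ cells 33 and 90 (16452), for Kit in K5- cells 22 and 93 (16413), and for the interaction 6 and 49 (16421).

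Library numbers 1 to 4, 5 to 8 and 9 to 12 each hold every population. The labels do not say that such a run shares a sort, so the pairing comes from the data. Libraries of the same run deviated together from their group means, at r of 0.263 to 0.369 between the groups compared for K5 in Kit+ cells, 0.153 to 0.207 for K5 in Kit- cells, 0.108 to 0.156 for Kit in K5+ cells and 0.299 to 0.408 for Kit in K5- cells. Each of these pairs was over 0.1, and by that the runs pair the libraries in the 4 pairwise comparisons. Over all 18 pairs within runs the median was 0.218 and the lowest 0.0928, in Kit+ K5- with Kit- K5+ libraries, which only the interaction sets together. The interaction thus falls short of the limit of 0.1, and its values with the block are given for comparison only. Deviations sum to 0 over the 3 libraries of a group, so positive values within runs push those between runs below 0. Pairs from different runs had a median of -0.131 and a highest value of 0.197. That highest value is above every pair for Kit in K5+ cells and above the lowest for K5 in Kit- cells. For 11 of 12 libraries the most similar deviations in another group were those of the same run. The common dispersion was 0.191 without and 0.118 with the block on runs. The fit without the block was kept as the main one, and values below are without it unless the block is named. Values with the block stand beside a result where it changed a call or moved a count of calls by over 1.5 times. The limit was first held to all 18 pairs, which did not meet it, and then to the pairs of each comparison. That the runs pair the libraries was settled in this way after the counts with the block had been seen.

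Total counts were 5589037 to 13724364 per library, so 3 counts, the floor used for a gene at 0, are well below 1 CPM. Counting intervals and floors cover counting error only. Genes with near-identical copies or overlapping exons are uncertain, since 50 nt reads cannot always be assigned. Among named genes these are Dcpp1, Dcpp2 and Dcpp3, Tpsab1 and Tpsb2, the haemoglobin genes, Smr3a, Top2a and Tfcp2l1 with short predicted or non-coding genes, Smgc with Muc19, Fgfr2 with Ctbp2 and Col3a1 with a predicted gene. With the strand setting unknown, the antisense partners of Krt5, Krt7, Lama3, Nid1, Nid2, Nr2f2, Nusap1, Ube2c, Fgf10, Gas1, Gli3, Dusp1, Myb, Ccnd1, Pdgfra, Rgs6, Slc22a3, Vstm2b and Inpp5b could add reads to them.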

Results

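The 12 libraries held 5589037 to 13724364 counts each. Genes in the files are identified by symbol. Correlations of log2 CPM between libraries of a group were 0.927 to 0.946 in Kit+ K5+, 0.907 to 0.948 in Kit+ K5-, 0.892 to 0.910 in Kit- K5+ and 0.942 to 0.956 in Kit- K5- cells. The leading principal component held 38.5% of the variance and set the Kit- K5- libraries apart, and 7 of 12 libraries had their nearest neighbour in their own group. Mitochondrial transcripts took 23.7% ± 6.60 of counts in Kit+ K5+, 17.2% ± 8.81 in Kit+ K5-, 28.0% ± 3.32 in Kit- K5+ and 9.07% ± 3.33 in Kit- K5- libraries (SD, n = 3).

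The gate genes were examined in each library. Kit (chromosome 5, 75574916 to 75656722) stood at 319 ± 15.9 CPM in Kit+ K5+ and 343 ± 89.5 CPM in Kit+ K5- cells, against 22.4 ± 6.22 and 14.7 ± 5.25 CPM in Kit- K5+ and Kit- K5- cells. It was higher in Kit+ cells by 3.83 ± 0.31 on the log2 scale among K5+ cells (adjusted p = 1.18e-04) and by 4.54 ± 0.32 among K5- cells (adjusted p = 1.32e-06). Krt5 (chromosome 15, 101707070 to 101712898), the keratin whose promoter drives Venus, had 5.25 ± 4.27 CPM in Kit+ K5+, 2.43 ± 2.16 in Kit+ K5-, 18.9 ± 4.86 in Kit- K5+ and 4.20 ± 3.17 in Kit- K5- cells. Its log2 difference between K5+ and K5- cells was 1.11 ± 0.85 among Kit+ cells (adjusted p = 0.829) and 2.18 ± 0.85 among Kit- cells (adjusted p = 0.0964), so neither passed the threshold. With a block on the runs of library numbers, the difference among Kit- cells passed (log2 2.77 ± 0.72, adjusted p = 0.0142). Venus itself was not analysed here. Cdh1 (chromosome 8, 106603351 to 106670246), which encodes the E-cadherin used to sort all 4 populations, had 799.9 ± 293 CPM in Kit+ K5+, 705 ± 203 in Kit+ K5-, 587 ± 64.3 in Kit- K5+ and only 173 ± 24.4 CPM in Kit- K5- cells. It was lower in Kit- K5- than in Kit- K5+ cells (log2 1.76 ± 0.28 for K5+ against K5-, adjusted p = 8.47e-04) and than in Kit+ K5- cells (log2 2.02 ± 0.28 for Kit+ against Kit-, adjusted p = 2.22e-04).

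**Figure D1:**
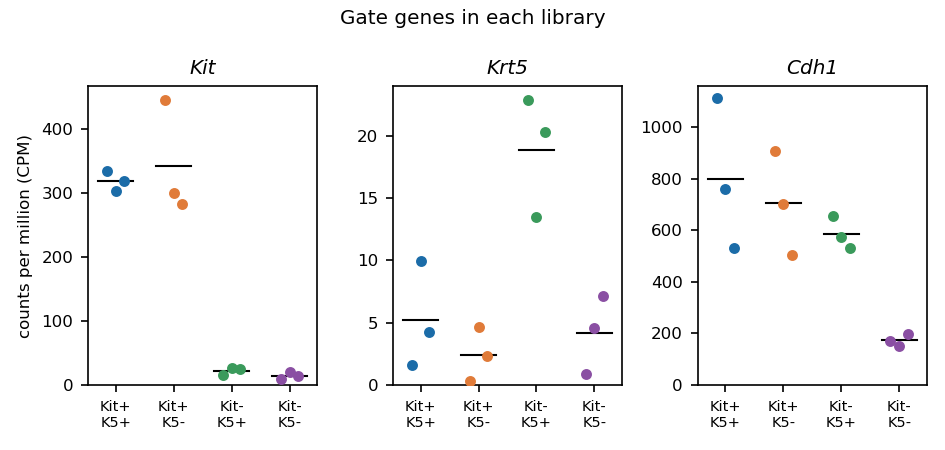
CPM of Kit, Krt5 and Cdh1 in each library, by population. Points are libraries (3 per population) and lines are means; Kit separates the Kit+ from the Kit- libraries, and Cdh1 is lowest in the Kit- K5- libraries, at a mean of 173 CPM.

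Within Kit+ cells, the libraries sorted for K5-Venus were compared with those without it, to ask what the K5 reporter separates among Kit+ cells. In this comparison 0 genes passed in edgeR's quasi-likelihood test without the block, and 54 with it, 2 higher and 52 lower in K5+ cells. Markers of basal cells passed in neither fit. Itga6, a laminin-binding integrin, had 504 ± 24.4 CPM in Kit+ K5+ and 362 ± 72.3 CPM in Kit+ K5- cells (log2 0.48 ± 0.31, adjusted p = 0.799), and Trp63, a transcription factor of basal epithelium, 223 ± 129 and 219.8 ± 167 CPM (log2 0.02 ± 0.75, adjusted p = 0.998). The proliferation genes Mki67 and Top2a had 1906 ± 507 and 882 ± 202 CPM in K5+ and 1528 ± 283 and 650.4 ± 130.5 CPM in K5- cells. Mast cell transcripts lay far apart on average, with Cpa3, a mast cell protease, at 10.1 ± 16.1 and 765 ± 1168 CPM and Hdc, the histamine-forming enzyme, at 3.75 ± 2.98 and 357 ± 569 CPM, and the single Kit+ K5- libraries ranged from 76.5 to 2114 CPM for Cpa3. Without the block neither gene passed (adjusted p = 0.275 and 0.183), and with it both were lower in K5+ cells (adjusted p = 0.00541 and 0.0278).

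No member of any of the 27 lists passed over all genes without the block. With it 8 of 8 mast cell, 4 of 13 leukocyte and macrophage and 1 of 20 acinar secretory genes were lower in Kit+ K5+ cells. Adjusted over the list alone, 8 of 8 mast cell genes and 10 of 13 leukocyte and macrophage genes were lower in Kit+ K5+ cells, as was 1 gene each of the Notch, endothelium and Schwann lists. Laptm5, a lysosomal protein of leukocytes, had 2.31 ± 3.12 CPM in K5+ and 72.1 ± 88.9 CPM in K5- cells (adjusted p = 0.310, and 1.10e-04 with the block). Camera called 7 lists in this comparison. Mitosis genes were shifted up (adjusted p = 3.59e-05 with the preset correlation and adjusted p = 0.331 with an estimated correlation), as were basal duct genes (adjusted p = 0.00302 with the preset correlation and adjusted p = 0.570 with an estimated correlation). Mast cell genes were shifted down (adjusted p = 3.78e-13 with the preset correlation and adjusted p = 0.271 with an estimated correlation), as were leukocyte and macrophage genes (adjusted p = 3.26e-07 with the preset correlation and adjusted p = 0.352 with an estimated correlation). The secretory gene Bpifa2 had 370.4, 25.3 and 0.388 CPM in the 3 K5+ libraries and 4432, 182 and 1.02 CPM in the K5- libraries of the same runs (adjusted p = 0.796, and 0.0389 with the block). Smgc had 165 ± 241 and 169 ± 245 CPM. Without the block, 1161 genes had unadjusted p below 0.05, where 851.5 would by chance, and the smallest adjusted p was 0.163. DESeq2 called 123 genes and limma-voom 0, and edgeR called 3 without Kit+ K5- replicate 2 and 4 without Kit+ K5- replicate 3.

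Within Kit- cells, K5+ libraries were compared with K5- libraries. In Kit- K5+ cells 15 of 18 basal duct and 6 of 19 luminal duct genes were higher. In Kit- K5- cells 14 of 16 mesenchyme, 5 of 7 erythroid, 8 of 13 leukocyte and macrophage and 6 of 10 neuron genes were higher. The 18 general epithelial genes also rose in Kit- K5+ cells, by a median log2 of 1.37. Medians were 2.64 for basal duct, 1.37 for luminal duct and salivary progenitor, 1.26 for stratified epithelium and 0.87 for Wnt targets. Apart from basal duct, a smaller epithelial share in Kit- K5- libraries could account for such rises, with equal levels of the general genes in every epithelial cell. Of 17030 genes, 1256 rose and 1550 fell in K5+ against K5- cells, 989 and 1320 of them by at least 2-fold, while with upper-quartile scaling more genes rose (1587) than fell (1329). Among basal duct genes, 15 of 18 measured genes rose and 1 fell (16 and 1 adjusted over the list alone). Itga6 rose by 2.80 ± 0.33 on the log2 scale (adjusted p = 9.57e-05). Lama3, a laminin chain of epithelial attachment, rose by 3.69 ± 0.47, Col17a1, a hemidesmosome collagen, by 3.01 ± 0.58, and Krt17, a basal keratin, by 3.31 ± 0.55. Krt14, the partner keratin of Krt5, rose from 11.98 ± 7.13 to 90.3 ± 39.5 CPM (adjusted p = 0.0218), and Trp63 from 67.6 ± 46.7 to 416 ± 102 CPM (adjusted p = 0.0384).

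The camera test placed basal duct genes up in Kit- K5+ cells (adjusted p = 9.49e-09 with the preset correlation and adjusted p = 0.352 with an estimated correlation). Of the salivary progenitor list, which shares 9 of its 16 genes with other lists, 10 of 15 measured genes rose and 1 fell (10 and 1 adjusted over the list alone), and Cd44, a hyaluronan receptor, fell from 117 ± 88.5 to 22.3 ± 6.97 CPM. In the distal end bud list, 10 of 16 measured genes rose and 0 fell (12 and 1 adjusted over the list alone). Elf5, a transcription factor of secretory epithelium, stood at log2 2.39 ± 0.63, with Fgf1 at 2.23 ± 0.33 and the FGF receptor Fgfr2 at 2.15 ± 0.52. In the luminal duct list, 6 of 19 measured genes rose and 0 fell (9 and 0 adjusted over the list alone). Tfcp2l1, a ductal transcription factor, rose from 57.8 ± 14.9 to 446 ± 135 CPM (adjusted p = 1.23e-05), and Krt7, a simple-epithelium keratin, from 2.23 ± 1.81 to 16.3 ± 1.00 CPM. In the stratified epithelium and desmosome list, 5 of 13 measured genes rose and 0 fell (6 and 0 adjusted over the list alone). The desmosomal genes Dsc3 and Perp stood at log2 3.67 ± 0.62 and 2.85 ± 0.35.

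In the myoepithelial and contractile list, 4 of 12 measured genes rose and 0 fell (5 and 0 adjusted over the list alone). Acta2, smooth muscle actin, had 704, 124 and 26.4 CPM in the 3 Kit- K5+ libraries against 23.8 ± 6.12 CPM in Kit- K5- cells, and its adjusted p of 0.0116 became 0.0835 without Kit- K5+ replicate 1 (log2 3.58 and 1.66). Actg2 and Myh11, further smooth muscle genes, rose by 3.44 ± 0.77 and 2.51 ± 0.63, and likewise lost their calls without that library. Among Wnt targets, 4 of 14 measured genes rose and 0 fell (5 and 0 adjusted over the list alone). Rnf43, a negative regulator of Wnt receptors, stood at 43.2 ± 1.58 against 8.13 ± 0.922 CPM (adjusted p = 8.45e-06) and Lgr6, an R-spondin receptor, at 46.3 ± 52.97 against 3.16 ± 0.818 CPM. Among mitosis genes, 13 of 22 measured genes rose and 0 fell (17 and 0 adjusted over the list alone). Kif23 and Nusap1, both parts of the dividing spindle, stood at log2 1.37 ± 0.22 and 1.20 ± 0.22. The genes with the largest folds upward were Smr3a, Lrp2, Dapl1, Chrm3, Rgs6, Dbx2, Lama3 and Adam28, at log2 3.68 to 4.46. Chrm3, the muscarinic receptor of salivary gland, had 49.2 ± 48.3 CPM in K5+ and 2.97 ± 0.627 CPM in K5- cells (adjusted p = 6.70e-04). Smr3a, a salivary secreted protein, had 11.5 and 0.518 CPM on average, and its adjusted p was 0.0543 without Kit- K5+ replicate 1.

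In the mesenchyme list, 0 of 16 measured genes rose and 14 fell (0 and 14 adjusted over the list alone) in Kit- K5+ against Kit- K5- cells. Col3a1, a fibrillar collagen of connective tissue (chromosome 1, 45311538 to 45349706), had 109 ± 20.2 CPM in Kit- K5+ and 4665 ± 1153 CPM in Kit- K5- cells (log2 -5.42 ± 0.46, adjusted p = 6.97e-06). Pdgfra, a mesenchymal growth factor receptor, had 11.3 ± 1.33 and 593 ± 142 CPM, and Lum, a matrix proteoglycan, 11.9 ± 3.65 and 508 ± 124 CPM. For leukocyte and macrophage genes, 0 of 13 measured genes rose and 8 fell (0 and 11 adjusted over the list alone). Lyz2, lysozyme, stood at 1.14 ± 0.968 and 86.8 ± 104 CPM. For erythroid genes, 0 of 7 measured genes rose and 5 fell (0 and 5 adjusted over the list alone). The beta-globin gene Hbb-bs stood at 7.18 ± 5.31 and 195 ± 239 CPM. For neuron genes, 0 of 10 measured genes rose and 6 fell (0 and 8 adjusted over the list alone). Gap43, a growth cone protein, stood at log2 -4.82 ± 0.67. Camera called mesenchyme down (adjusted p = 3.77e-15 with the preset correlation and adjusted p = 0.201 with an estimated correlation). The genes with the largest downward folds were C1qc, C1qtnf2, Cpa1, C5ar1, Ccl9, Tmem132e, Agtr1a and Tspan11. C1qc, a complement gene of macrophages, was lower in K5+ cells by a ratio of 296 (95% interval from counting 81.8 to 2447), and by 114 without Kit- K5- replicate 1. The angiotensin receptor Agtr1a had 0.171 ± 0.190 and 22.6 ± 10.3 CPM (adjusted p = 7.05e-05).

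In the basement membrane list, 8 of 23 measured genes rose and 3 fell (10 and 4 adjusted over the list alone). The nidogens Nid1 and Nid2 fell, with log2 values of -4.25 ± 0.43 and -5.06 ± 0.36. In the retinoic acid list, 1 of 13 measured genes rose and 6 fell (2 and 6 adjusted over the list alone). Aldh1a2, a retinoic acid synthesis enzyme, stood at 3.62 ± 3.33 and 143 ± 42.2 CPM. In the dissociation stress list, 1 of 19 measured genes rose and 4 fell (1 and 5 adjusted over the list alone, 2 and 10 with the block), including Dusp1 and Socs3 at log2 -1.98 ± 0.46 and -1.69 ± 0.45. Camera called this list down only with the block (adjusted p = 0.0154 with the block and the preset correlation and adjusted p = 0.493 with an estimated correlation). Genes that rose and fell in the other lists were acinar secretory differentiation 6 and 2 of 20 (7 and 2 adjusted over the list alone), FGF and ERK feedback 3 and 1 of 18 (4 and 1 adjusted over the list alone, 5 and 2 with the block) and Hedgehog 1 and 0 of 10 (1 and 0 adjusted over the list alone, 1 and 3 with the block). Counts in that order were also Notch 3 and 3 of 14 (3 and 3 adjusted over the list alone), ErbB ligands and receptors 2 and 0 of 11 (2 and 0 adjusted over the list alone) and DNA replication 1 and 0 of 24 (0 and 0 adjusted over the list alone, 3 and 3 with the block). Further counts were ER folding and secretion 1 and 4 of 26 (1 and 4 adjusted over the list alone, 1 and 8 with the block), endothelium 0 and 0 of 8 (0 and 0 adjusted over the list alone, 0 and 1 with the block) and mast cell 0 and 1 of 8 (0 and 1 adjusted over the list alone, 1 and 2 with the block). Counts in that order were also Schwann and glia 1 and 2 of 10 (1 and 6 adjusted over the list alone, 1 and 5 with the block) and skeletal muscle 0 and 2 of 7 (0 and 2 adjusted over the list alone, 1 and 2 with the block). In the melanocyte list 0 genes passed, and 0 adjusted over the list alone. Without 1 library the count of 2806 genes fell to 1362 (Kit- K5- replicate 1) or 1642 (Kit- K5- replicate 2), and 39 of the 51 calls named passed without any 1 library. Egfr, Elf5, Fgfr2, Krt7, Krt14, Trp63, Socs3 and C5ar1 are among the 12 that did not, and the log2 differences of Egfr, Kif23 and Nusap1 turned below 0 when libraries were scaled to general epithelial genes.

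**Figure D2:**
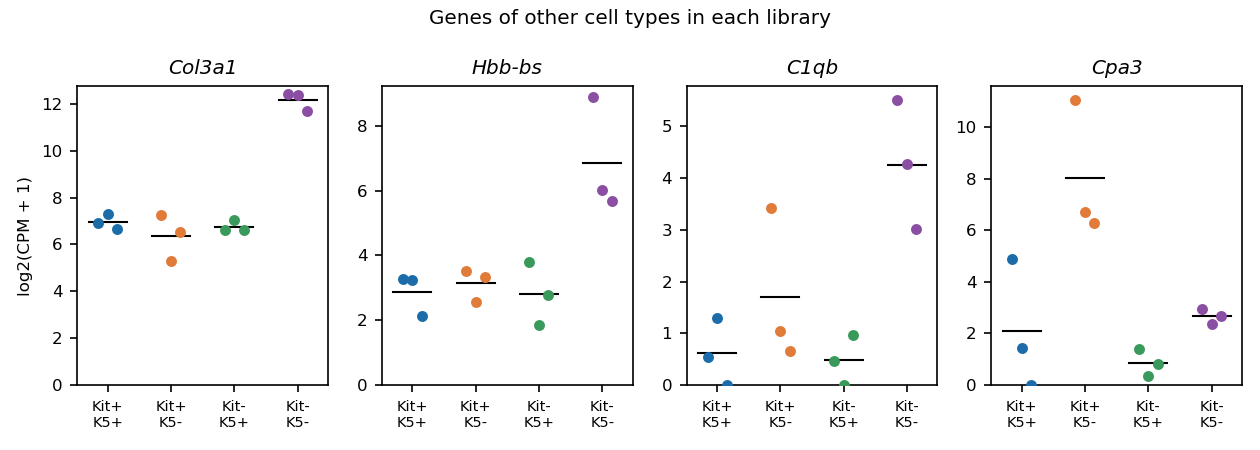
Log2(CPM + 1) of Col3a1 (mesenchyme), Hbb-bs (red cells), C1qb (macrophages) and Cpa3 (mast cells) in each library, by population. Points are libraries, 3 per population, and lines are means of the plotted log2 values; the first 3 genes are highest in the Kit- K5- libraries and Cpa3 in the Kit+ K5- libraries.

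**Figure D3:**
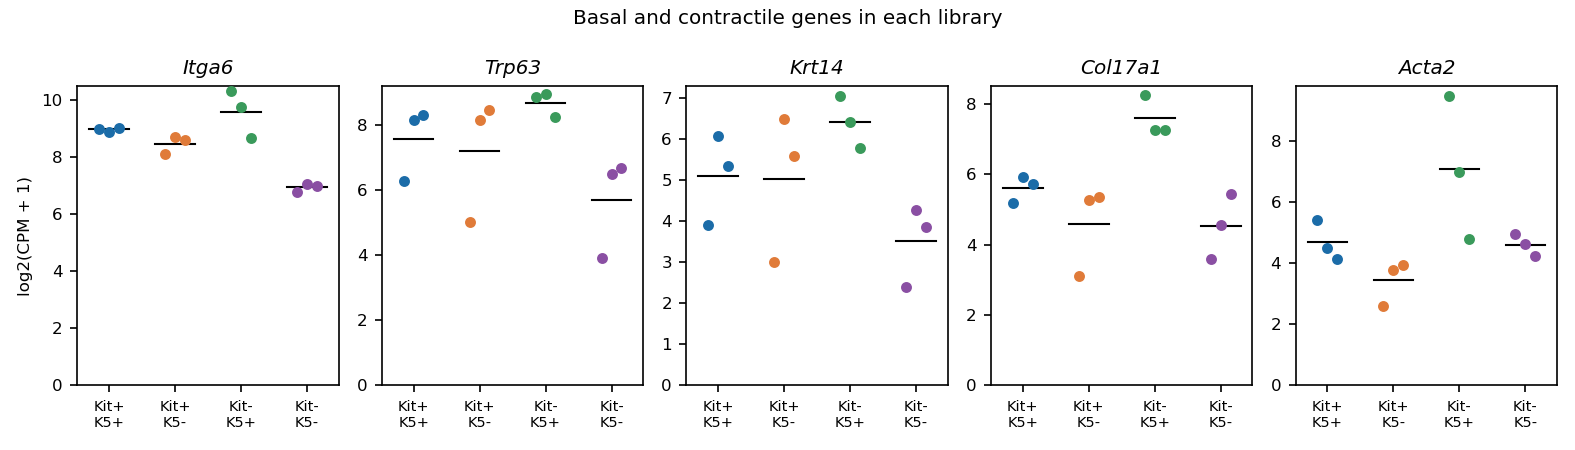
Log2(CPM + 1) of Itga6, Trp63, Krt14, Col17a1 and Acta2 in each library, by population. Points are libraries, 3 per population, and lines are means of the plotted log2 values; Acta2 spans 26.4 to 704 CPM among the Kit- K5+ libraries.

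Among K5+ cells, Kit+ libraries were compared with Kit- libraries. In Kit+ K5+ cells 57 genes were higher, among them Pou2f3 and Myb, and 55 were lower, among them Col11a1 and Igfbp5. With the block on runs 433 were higher and 355 lower. Of 24 named calls, those of Kit, Col11a1 and Tfcp2l1 passed without any 1 library. Apart from Kit, the largest upward folds were those of Fam167a, Rassf6, Pou2f3, Cldn7, Inpp5b, Csn1s1 and Podxl. Pou2f3 (chromosome 9, 43123939 to 43210369), a POU-domain transcription factor, had 129 ± 65.5 CPM in Kit+ and 7.32 ± 5.02 CPM in Kit- cells (log2 4.10 ± 0.61, adjusted p = 0.0182). Cldn7, a tight junction claudin, had 29.6 ± 18.6 and 3.91 ± 1.85 CPM, and Csn1s1, a casein, 88.6 ± 32.4 and 13.7 ± 8.08 CPM. Myb, a transcription factor of progenitor cells, rose by 1.73 ± 0.26 (adjusted p = 0.0182), Cd44 by 2.47 ± 0.47 and the receptor Erbb3 by 1.26 ± 0.23.

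Among the largest downward folds in Kit+ K5+ cells were those of Pgm5, Bnc2, Speg, Col11a1, Sgk3, Igfbp5 and Cpe. Igfbp5, a binding protein of insulin-like growth factors, fell from 2508 ± 459 to 341 ± 112 CPM, and Col11a1, a fibrillar collagen, from 35.2 ± 3.42 to 4.09 ± 0.154 CPM (adjusted p = 2.78e-04). Egfr, the epidermal growth factor receptor, fell by 3.10-fold (adjusted p = 0.0407), while Erbb3 of the same family rose. In the basal duct list, 0 of 18 measured genes rose and 2 fell (0 and 7 adjusted over the list alone, 0 and 4 with the block), Wnt4 by 6.14-fold and Lama3 by 4.81-fold. In the luminal duct list, 1 of 19 measured genes rose and 1 fell (3 and 2 adjusted over the list alone, 2 and 2 with the block), Tfcp2l1 falling from 446 ± 135 to 99.1 ± 14.6 CPM. In the myoepithelial and contractile list, 0 of 12 measured genes rose and 1 fell (0 and 8 adjusted over the list alone, 0 and 4 with the block), the gene that fell over all genes being Cald1, which binds actin.

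In the mitosis list, 1 of 22 measured genes rose and 0 fell (9 and 0 adjusted over the list alone, 7 and 0 with the block). Aurkb, a mitotic kinase, stood at 126 ± 19.02 and 53.3 ± 8.22 CPM. In the DNA replication list, 0 of 24 measured genes rose and 0 fell (18 and 0 adjusted over the list alone, 9 and 0 with the block). Camera called DNA replication up (adjusted p = 1.99e-11 with the preset correlation and adjusted p = 0.296 with an estimated correlation), mitosis up (adjusted p = 7.07e-07 with the preset correlation and adjusted p = 0.275 with an estimated correlation) and myoepithelial genes down (adjusted p = 2.48e-04 with the preset correlation and adjusted p = 0.420 with an estimated correlation). In the list of ER folding and secretion, 0 of 26 measured genes rose and 0 fell (3 and 0 adjusted over the list alone, 3 and 0 with the block), and camera called it up (adjusted p = 2.23e-04 with the preset correlation and adjusted p = 0.352 with an estimated correlation). Median log2 values were 0.71 for DNA replication, 0.48 for mitosis and 0.33 for ER folding and secretion. Scaling to general epithelial genes moved the median of all genes by -0.65 here, with 12 genes then called higher and 836 lower. Whether a difference in epithelial share gives the rises of these lists was not tested. In the salivary progenitor list, 2 of 15 measured genes rose and 0 fell (2 and 0 adjusted over the list alone), in the basement membrane list 0 of 23 measured genes rose and 1 fell (0 and 1 adjusted over the list alone), and in the ErbB list 1 of 11 measured genes rose and 1 fell (1 and 1 adjusted over the list alone). Col3a1, of the mesenchyme list, had 125 ± 28.4 and 109 ± 20.2 CPM (adjusted p = 0.817). Genes that rose and fell in the other lists were distal end bud 0 and 0 of 16 (0 and 0 adjusted over the list alone, 2 and 1 with the block), acinar secretory differentiation 0 and 0 of 20 (0 and 0 adjusted over the list alone, 4 and 0 with the block) and stratified epithelium and desmosome 0 and 0 of 13 (1 and 3 adjusted over the list alone, 0 and 2 with the block). Counts in that order were also FGF and ERK feedback 0 and 0 of 18 (1 and 0 adjusted over the list alone, 2 and 0 with the block), Wnt targets 0 and 0 of 14 (0 and 0 adjusted over the list alone, 1 and 0 with the block) and Hedgehog 0 and 0 of 10 (0 and 3 adjusted over the list alone, 0 and 1 with the block). Further counts were retinoic acid 0 and 0 of 13 (0 and 1 adjusted over the list alone, 0 and 1 with the block), mesenchyme 0 and 0 of 16 (0 and 2 adjusted over the list alone, 0 and 2 with the block) and endothelium 0 and 0 of 8 (0 and 1 adjusted over the list alone, 0 and 1 with the block). Counts in that order were also mast cell 0 and 0 of 8 (0 and 0 adjusted over the list alone, 3 and 0 with the block), neuron 0 and 0 of 10 (0 and 0 adjusted over the list alone, 0 and 1 with the block) and Schwann and glia 1 and 0 of 10 (1 and 0 adjusted over the list alone). Further counts were skeletal muscle 0 and 0 of 7 (0 and 2 adjusted over the list alone, 0 and 1 with the block). In the Notch, dissociation stress, leukocyte and macrophage, melanocyte and erythroid lists 0 genes passed, and 0 adjusted over the list alone. Camera called acinar secretory genes up only with the block (adjusted p = 0.00606 with the block and the preset correlation and adjusted p = 0.272 with an estimated correlation), and Bpifa2 of that list had 132 ± 207 and 23.2 ± 38.8 CPM (adjusted p = 0.589, and 0.0247 with the block). The count of 112 genes moved with single libraries, to 4 and 5 without Kit+ K5+ or Kit- K5+ replicate 1, 12 and 11 without their replicates 2, 43 and 63 without their replicates 3, 70, 31 and 58 without Kit- K5- replicates 1, 2 and 3, and 240 and 69 without Kit+ K5- replicates 1 and 3. DESeq2 called 1092 genes (361 higher and 731 lower) against 58 by limma-voom (34 and 24) and 72 with only the 2 groups fitted (27 and 45). Upper-quartile factors gave 35 higher and 64 lower, so which direction held more genes depended on the processing.

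Among K5- cells, Kit+ libraries were compared with Kit- libraries. In Kit+ K5- cells 8 of 16 distal end bud, 7 of 20 acinar secretory, 19 of 22 mitosis and 7 of 8 mast cell genes were higher. There 15 of 16 mesenchyme, 5 of 7 erythroid and 6 of 10 neuron genes were lower. The 18 general epithelial genes also rose here, by a median log2 of 2.24. Medians were smaller for distal end bud (1.35), acinar secretory (1.72), luminal duct (2.04) and mitosis genes (1.07). Scaling to the general epithelial genes moved the median of all genes by -2.22 here, with 32 genes then called higher and 13125 lower. This scaling assumes equal levels of those genes in every epithelial cell, which was not tested. The scaling factor from those genes was 2.91, 1.903 and 1.14 in Kit+ K5- replicates 1 to 3. Unless the epithelial share fell as much, this goes against equal levels in Kit+ K5- cells. Only with equal levels could a smaller epithelial share in the Kit- K5- libraries be read as accounting for the rises of these lists. Overall 1729 genes rose and 1895 fell, 1247 and 1619 of them by at least 2-fold, while with upper-quartile scaling more genes rose (1974) than fell (1751). In the distal end bud list, 8 of 16 measured genes rose and 0 fell (10 and 2 adjusted over the list alone, 10 and 1 with the block). Elf5 stood at log2 3.13 ± 0.65, Cldn10, a claudin, at 2.96 ± 0.53, and the FGF-responsive factors Etv4 and Etv5 at 1.95 ± 0.36 and 1.88 ± 0.49. In the acinar secretory list, 7 of 20 measured genes rose and 0 fell (10 and 1 adjusted over the list alone, 14 and 2 with the block). Dcpp1, Dcpp2 and Dcpp3, salivary secreted proteins encoded side by side on chromosome 17 and hard to tell apart by short reads, rose by 4.69 ± 0.76, 4.31 ± 0.74 and 4.33 ± 0.75, and Spdef, a factor of secretory cells, by 3.04 ± 1.03 (adjusted p = 0.0490). Spdef and Etv5 lost their calls in 7 and 2 of the 12 fits that left out 1 library. Of the 20 acinar genes 11 also differed between runs of library numbers, in a test chosen after the values were seen. In the luminal duct list, 11 of 19 measured genes rose and 0 fell (13 and 0 adjusted over the list alone). The potassium channel Kcnn4 stood at 91.7 ± 54.5 against 11.7 ± 8.32 CPM and the epithelial factor Grhl3 at 41.3 ± 10.1 against 7.18 ± 5.22 CPM.

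In the mitosis list, 19 of 22 measured genes rose and 0 fell (19 and 0 adjusted over the list alone). Ube2c and Birc5 stood at 276 ± 30.8 and 63.6 ± 12.4 CPM against 100.4 ± 31.4 and 23.9 ± 5.33 CPM. Camera called mitosis up (adjusted p = 2.91e-09 with the preset correlation and adjusted p = 0.271 with an estimated correlation). In the DNA replication list, 11 of 24 measured genes rose and 0 fell (16 and 0 adjusted over the list alone). Rrm2, a ribonucleotide reductase subunit, stood at log2 2.02 ± 0.30 and Uhrf1 at 1.25 ± 0.24, and the cyclin gene Ccnd1 rose by 2.27 ± 0.37. The transcription factor Myb rose from 14.3 ± 0.984 to 118 ± 15.9 CPM (adjusted p = 6.64e-06), Pou2f3 from 1.06 ± 0.827 to 44.6 ± 13.04 CPM, and Erbb3 from 43.2 ± 10.95 to 186 ± 13.8 CPM, while Egfr fell from 125 ± 9.01 to 59.6 ± 27.02 CPM. In the salivary progenitor list, 6 of 15 measured genes rose and 0 fell (8 and 0 adjusted over the list alone). In the stratified epithelium and desmosome list, 6 of 13 measured genes rose and 0 fell (6 and 0 adjusted over the list alone). In the Wnt list, 4 of 14 measured genes rose and 1 fell (4 and 1 adjusted over the list alone). Rnf43 stood at log2 2.56 ± 0.21 and Tnfrsf19 at 2.89 ± 0.82. In the ErbB list, 2 of 11 measured genes rose and 2 fell (3 and 2 adjusted over the list alone).

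Of the 8 largest upward folds in Kit+ K5- cells, 5 were of mast cell genes. In that list 7 of 8 measured genes rose and 0 fell (7 and 0 adjusted over the list alone). Cpa3 (chromosome 3, 20215620 to 20242181) had 2114, 104 and 76.5 CPM in the Kit+ K5- libraries and 5.48 ± 1.30 CPM in Kit- K5- cells (log2 7.12 ± 1.55, adjusted p = 0.00540). Mcpt4, a mast cell protease, had 0 counts in every Kit- K5- library and was at least 342-fold higher in Kit+ K5- cells, with the floor of 3 counts taken over the group. Without Kit+ K5- replicate 1 this was at least 57.4-fold. Cma1, Tpsab1 and Tpsb2, further mast cell proteases, had 343 ± 549, 139 ± 226 and 183 ± 303 CPM against 0.0874 ± 0.151, 0.113 ± 0.135 and 0.199 ± 0.197 CPM. Maob, a monoamine oxidase, and Slc22a3, an organic cation transporter, also stood among the 8 largest upward folds, at 34.7 ± 47.3 and 12.96 ± 14.97 CPM.

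In the mesenchyme list, 0 of 16 measured genes rose and 15 fell (0 and 15 adjusted over the list alone) in Kit+ K5- against Kit- K5- cells, and camera called the list down (adjusted p = 1.43e-16 with the preset correlation and adjusted p = 0.201 with an estimated correlation). Dcn, a matrix proteoglycan, had 27.99 ± 14.3 and 1398 ± 318 CPM, and Fgf10, a mesenchymal growth factor for the gland epithelium, 3.04 ± 1.53 and 151 ± 30.3 CPM. The largest downward folds were those of Hba-x, Hbb-y, Rbp4, Kera, Vstm2b, Kcne4, Slitrk6 and Epha3. Hba-x, an embryonic globin, had 0 counts in every Kit+ K5- library and was at least 120.2-fold lower there, and Hbb-y, another, was lower by a ratio of 647 (95% interval from counting 116 to 25595). Without Kit+ K5- replicate 1, where the single Hbb-y count lies, these were at least 76.2-fold and at least 137-fold lower. Slitrk6 (chromosome 14, 110748580 to 110755149), a neuronal adhesion protein, had 1.70 ± 0.693 and 132 ± 15.2 CPM, and Kera, a matrix proteoglycan, 1.57 ± 0.911 and 157 ± 45.4 CPM. In the erythroid list, 0 of 7 measured genes rose and 5 fell (0 and 6 adjusted over the list alone), in the neuron list 0 of 10 measured genes rose and 6 fell (0 and 8 adjusted over the list alone), and in the leukocyte and macrophage list 0 of 13 measured genes rose and 2 fell (0 and 2 adjusted over the list alone, 0 and 4 with the block). In the Hedgehog list, 1 of 10 measured genes rose and 5 fell (1 and 5 adjusted over the list alone). Gas1, Gli2 and Gli3 stood at log2 -2.78 ± 0.32, -1.96 ± 0.53 and -1.32 ± 0.38. In the retinoic acid list, 0 of 13 measured genes rose and 6 fell (0 and 8 adjusted over the list alone, 1 and 7 with the block). Aldh1a2 stood at log2 -5.70 ± 0.73. In the dissociation stress list 0 of 19 measured genes rose and 6 fell (0 and 6 adjusted over the list alone, 1 and 11 with the block). Fos stood at -1.35 ± 0.37 and Fosb at -2.41 ± 0.67. Genes that rose and fell in the other lists were basal duct 6 and 1 of 18 (8 and 1 adjusted over the list alone, 9 and 2 with the block), myoepithelial and contractile 0 and 1 of 12 (0 and 1 adjusted over the list alone, 0 and 2 with the block) and FGF and ERK feedback 6 and 2 of 18 (7 and 4 adjusted over the list alone). Counts in that order were also Notch 1 and 2 of 14 (3 and 2 adjusted over the list alone, 3 and 2 with the block), ER folding and secretion 3 and 4 of 26 (4 and 4 adjusted over the list alone, 5 and 4 with the block) and basement membrane 2 and 5 of 23 (4 and 6 adjusted over the list alone, 6 and 6 with the block). Further counts were endothelium 0 and 2 of 8 (0 and 3 adjusted over the list alone), Schwann and glia 1 and 0 of 10 (2 and 3 adjusted over the list alone, 1 and 2 with the block) and skeletal muscle 0 and 2 of 7 (0 and 2 adjusted over the list alone, 1 and 2 with the block). In the melanocyte list 0 genes passed, and 0 adjusted over the list alone. Without 1 library the count of 3624 genes fell most to 2123 (Kit+ K5- replicate 2), 2197 (Kit- K5- replicate 1) and 2398 (Kit- K5- replicate 2). Of 52 named calls 42 passed without any 1 library, the others being those of Slc22a3, Etv5, Spdef, Krt17, Tnfrsf19, Gli2, Gli3, Egfr, Fos and Fosb. The log2 differences of Cdh1, Etv4, Etv5, Krt17, Ccnd1, Erbb3, Ube2c, Birc5, Rrm2 and Uhrf1 turned below 0 with scaling to general epithelial genes. Of these, Birc5 and Uhrf1 were then called lower in Kit+ K5- cells (adjusted p = 0.0408 and 0.0323).

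**Figure D4:**
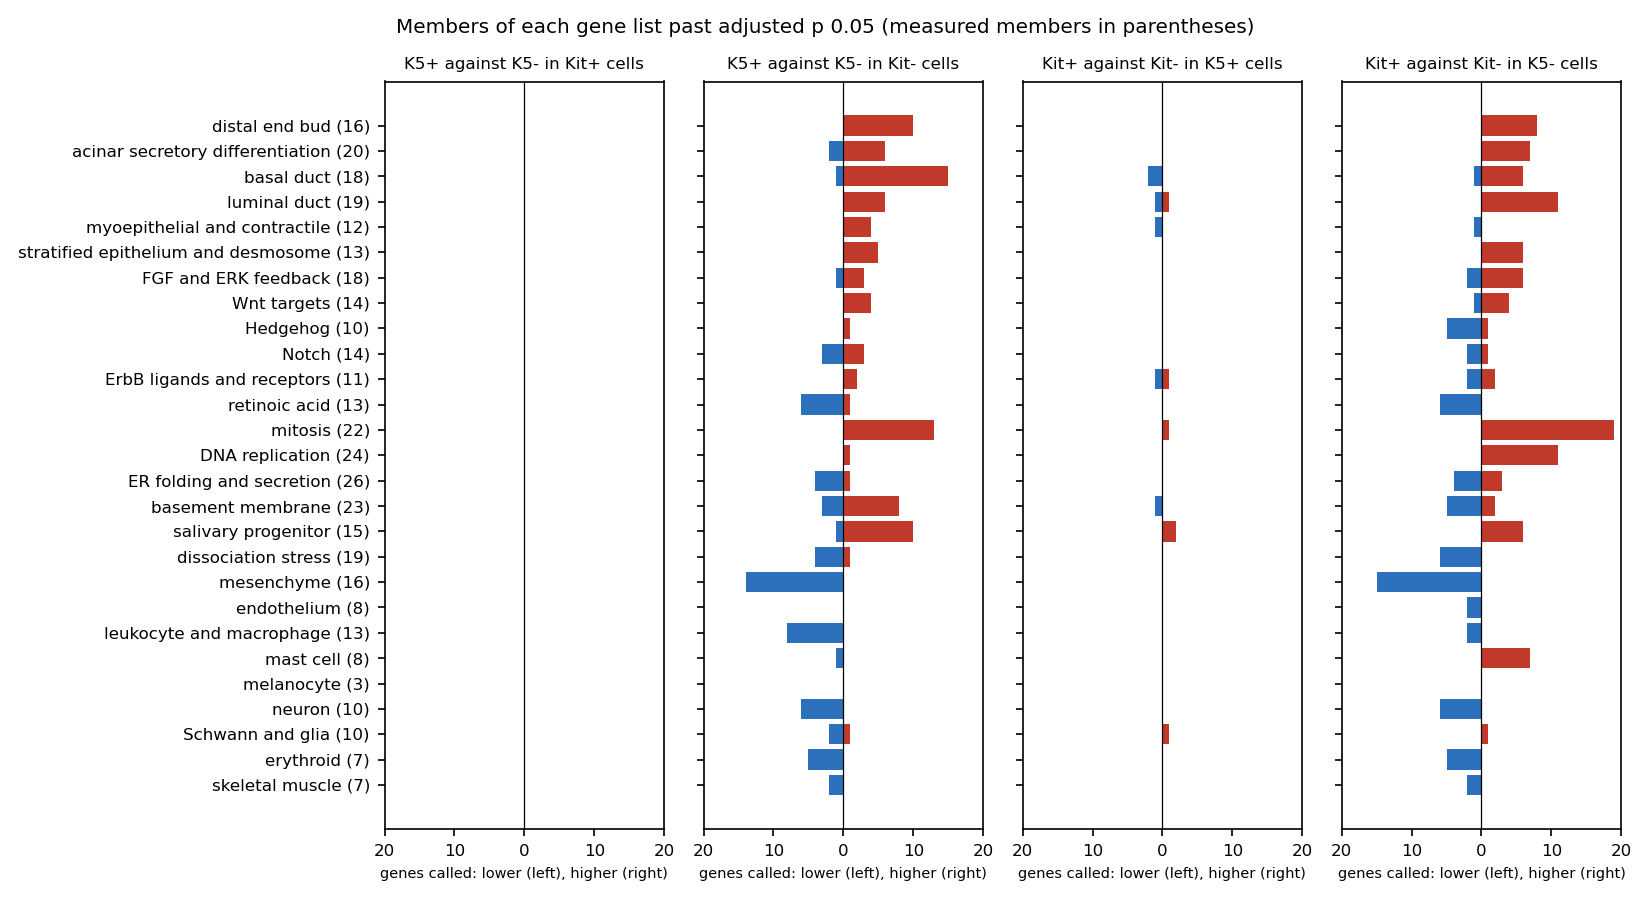
Number of members of each of the 27 gene lists past an adjusted p of 0.05 without the block, higher to the right and lower to the left, in the 4 pairwise comparisons, with measured members in parentheses. Bars start at 0; mitosis reaches 19 of 22 higher in Kit+ against Kit- among K5- cells, and the panel for K5 among Kit+ cells is empty.

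The interaction asks whether the difference between K5+ and K5- cells depended on Kit. It was called for 684 genes, 478 with a higher and 206 with a lower K5 difference among Kit+ than among Kit- cells, and with the block on runs for 1418, 824 and 594. Over the 4 groups that the interaction uses, the runs fell short of the limit for pairing. Among the 10 smallest adjusted p-values were those of Slitrk6, Nr2f2, Clcn5, Itm2a, Nid2, Kera, Lpl, Chst2 and Adamts12. These genes had their highest mean in Kit- K5- cells. Nr2f2, a nuclear receptor of mesenchyme, had 279 ± 15.3 CPM there against 22.1 ± 3.61, 15.8 ± 1.93 and 28.4 ± 5.78 CPM in Kit+ K5+, Kit+ K5- and Kit- K5+ cells. Itm2a and Lpl, lipoprotein lipase, reached 756 ± 193 and 443 ± 161 CPM in Kit- K5- cells, and Clcn5, a chloride transporter, 472 ± 32.1 CPM. In the mesenchyme list, 11 of 16 genes had a higher and 0 a lower K5 difference among Kit+ cells (14 and 0 adjusted over the list alone; camera adjusted p = 2.11e-18 with the preset correlation and adjusted p = 0.201 with an estimated correlation). In the basal duct list the counts were 0 and 4 of 18 (1 and 13 adjusted over the list alone, 1 and 11 with the block; camera adjusted p = 4.65e-06 with the preset correlation and adjusted p = 0.397 with an estimated correlation). Camera called acinar secretory genes down only with the block (adjusted p = 0.0397 with the block and the preset correlation and adjusted p = 0.301 with an estimated correlation). It likewise called dissociation stress up (adjusted p = 0.00810 with the block and the preset correlation and adjusted p = 0.476 with an estimated correlation) and leukocyte and macrophage genes up (adjusted p = 0.0167 with the block and the preset correlation and adjusted p = 0.493 with an estimated correlation). Without Kit- K5- replicate 1, Kit- K5- replicate 2 or Kit+ K5+ replicate 2 the count was 370, 396 or 416, and the 9 genes named first here passed in each of the 12 fits that left out 1 library.

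The comparisons were set side by side. The log2 differences of K5 in Kit+ and in Kit- cells, which share no libraries, correlated across 17030 genes at r = 0.106 and rho = 0.133, where genes are not independent replicates. Since 0 genes were called in Kit+ cells without the block, no overlap of calls could be counted there. With the block 40 of the 52 genes lower in Kit+ K5+ cells were also lower in Kit- K5+ cells, where 6.67 would be by chance for independent lists, and 1 was higher. Among the 52 were 8 mast cell and 4 leukocyte and macrophage genes. Here and for Kit below, both sets of calls came from 1 fit with a shared estimate of spread. The lists are thus not independent, and the numbers by chance may be too low. For Kit, which also shares no libraries between K5+ and K5- cells, 44 genes were higher in both comparisons, where 5.79 would be by chance for independent lists, and 35 were lower in both against 6.12. Called in opposite directions were 2 and 1 genes. With the block 328 were higher in both against 62.1 by chance, 188 lower in both against 52.8, and 9 and 6 were called in opposite directions.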

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

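Of the tests below, the correlation among mast cell genes and the counts of erythroid and macrophage genes were chosen after those values had been seen, and the scaling to general epithelial genes and the thinning with the block were added after seeing the data. The predictions on depth and on the epithelial share were written after those fits had been run and before their values were read. What drew attention here was a difference between groups in the effect of K5, by the interaction test.

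The interaction was called for 684 genes, and for 1418 with the block on runs. Of the genes named in the report, 43 were called, 28 with a higher and 15 with a lower K5 difference among Kit+ than among Kit- cells, and 69 with the block, these 43 among them. Their fitted log2 interaction values were Hbb-y 11.38, Cpa1 9.21, C1qtnf2 7.96, Rbp4 7.59, Kera 7.49, Tmem132e 7.28, Agtr1a 6.98, Slitrk6 6.50, Kcne4 6.48, Chst2 6.23, Lum 6.10, Col3a1 5.84, Epha3 5.69, Pdgfra 5.65, Dcn 5.65, Tspan11 5.57, Nid2 5.53, Fgf10 5.37, Lpl 5.17, Itm2a 5.04, Adamts12 4.90, Vstm2b 4.80, Aldh1a2 4.77, Hbb-bs 4.50, Nid1 4.35, Nr2f2 3.79, Clcn5 3.30, Cd44 2.76 for those that were higher. They were Mcpt4 -15.90, Slc22a3 -7.34, Lrp2 -5.03, Dcpp1 -4.24, Dcpp3 -3.85, Chrm3 -3.75, Dcpp2 -3.75, Krt17 -3.43, Perp -2.81, Lama3 -2.56, Rnf43 -2.40, Tfcp2l1 -2.34, Itga6 -2.32, Etv4 -1.90, Cdh1 -1.58 for those that were lower. The values of Mcpt4, Hbb-y, Rbp4, Cpa1, C1qtnf2 and Tmem132e rest on a group with at most 3 counts and depend on the fit. Camera called 11 lists for the interaction, with median log2 values of 4.55 for mesenchyme, 4.50 for erythroid, 3.25 for neuron, 1.63 for Schwann and glia, -4.36 for mast cell (-4.32 without the 2 members at 0 in a group), -2.21 for basal duct, -1.56 for stratified epithelium and desmosome, -1.49 for distal end bud, -1.38 for luminal duct, -1.31 for salivary progenitor and -0.50 for mitosis. With an estimated correlation their adjusted p ranged from 0.201 to 0.479. Scaling to general epithelial genes moved the median of all genes by 1.57 for the interaction. The list medians from -1.56 to -0.50 are smaller in size than this, and those of basal duct and mast cell genes larger. With equal levels of the general genes in every epithelial cell, a smaller epithelial share in Kit- K5- libraries could account for the smaller ones. The call of Schwann and glia ended with the block (adjusted p = 0.0590 with the block and the preset correlation and adjusted p = 0.432 with an estimated correlation).

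Other groupings of the libraries were tried, without the block. Of 100 groupings of the 12 libraries, the real one included, 2 called as many interaction genes as the real 684. The other one called 1557 and kept all 3 Kit- K5- libraries together, as did a grouping with 458 calls. Besides the real grouping, only these 2 kept them together. Any call at all was made in 4 groupings besides the real one, the others of these having 2 calls and 1 call. Calls in number thus appeared only with these libraries together, and may follow them rather than the interaction as such. For the pairwise comparisons, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real counts were 2806 (K5 in Kit- cells), 112 (Kit in K5+ cells) and 3624 (Kit in K5- cells), and the highest count of the other splits was 0 in each; 1 of the 10 splits reached the real count. For K5 in Kit+ cells all 10 splits gave 0.

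In Kit- K5- libraries 14 of 16 mesenchyme, 5 of 7 erythroid, 8 of 13 leukocyte and macrophage and 6 of 10 neuron genes were higher than in Kit- K5+ libraries. A difference in depth is argued against, since 14 mesenchyme genes were still called lower in Kit- K5+ cells with every library thinned to the smallest total, and 14 with the block as well. A mesenchyme-like state of the epithelial cells would not by itself give the 5 erythroid and 8 macrophage genes called in the same direction. Those counts are part of the pattern and had been seen, and they do not show which cells carry the mesenchyme genes. Such a state therefore stays open as a source of the mesenchyme genes. A candidate explanation is cells of other types in place of part of the epithelial cells, although the sort on E-cadherin should remove them: the 18 general epithelial genes had a median log2 ratio of 1.37 in Kit- K5+ and 2.24 in Kit+ K5- against Kit- K5- libraries (1.23 to 1.64 and 2.02 to 2.55 without 1 library), and the mesenchyme list shares 0 genes with other lists, with 11 of its 16 genes also at 10 CPM or more in Kit+ K5+ libraries. Lower transcription of epithelial genes in Kit- K5- epithelial cells would give the same median and stays open.

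In Kit+ K5- libraries 7 of 8 mast cell genes were higher than in Kit- K5- libraries, with most of their counts in replicate 1. Summed CPM of these genes were 5358, 239 and 131 in the 3 Kit+ K5- libraries and at most 49.2 in any other library. Of the 8 genes, 1 had a mean of 10 CPM or more in Kit+ K5+ libraries, and the list shares 0 genes with other lists. Mast cells carry Kit and so would pass that gate, and whether they would pass the one for E-cadherin was not tested. Mast cells in the sorted population and expression of these genes by Kit+ epithelial cells cannot be told apart. Each of the 8 genes correlated with the mean of the others over the 12 libraries at r of at least 0.744, but the Kit+ K5- libraries fix that value whichever cells express the genes, and a difference between Kit+ epithelial cells with and without K5 was not tested against this.

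In Kit- K5+ cells 15 of 18 basal duct, 10 of 16 distal end bud and 13 of 22 mitosis genes were higher than in Kit- K5- cells (adjusted p = 0.352, 0.321 and 0.275 for the lists with an estimated correlation). Thinning left 15 basal duct, 11 distal end bud and 13 mitosis genes called higher (16, 11 and 16 with the block), which argues against depth. Scaling to general epithelial genes assumes equal levels of the 18 genes in every epithelial cell. That was not tested, and the readings below hold only under this assumption. The scaling factor from these genes differed within the Kit+ populations. It was 2.195, 1.496 and 0.957 in Kit+ K5+ and 2.91, 1.903 and 1.14 in Kit+ K5- replicates 1 to 3. Unless the epithelial share fell as much, this goes against equal levels in Kit+ cells. In the Kit- libraries compared here the factor varied less, from 0.847 to 1.007 in Kit- K5+ and from 0.377 to 0.443 in Kit- K5-. A smaller epithelial share in the Kit- K5- libraries could account for the distal end bud genes. Their median log2 ratio went from 1.47 to 0.0378 with this scaling and their calls from 10 to 0. For basal duct genes a smaller share is argued against as the whole cause, under that assumption only. The median went from 2.64 to 1.18 (0.68 to 1.42 without 1 library) and 6 rather than 15 genes were called, at smaller folds. The difference in K5 that the sort names was not tested against this, and Krt5 passed only with the block (adjusted p = 0.0964 without it and 0.0142 with it). For mitosis genes the median went from 0.80 to -0.63 (-0.74 to -0.53 without 1 library) and the calls from 13 to 0. This median is outside what was predicted with or without a smaller share, so the prediction decides neither way. Under that assumption no rise of mitosis genes was left, and a smaller share could account for the 13 calls. It would not by itself give a median below 0.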

How the results depend on the processing

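Leaving out libraries 1 to 4, 5 to 8 or 9 to 12, scaling to general epithelial genes and thinning with the block were tried after seeing the data. With DESeq2 size factors, upper-quartile factors, the stricter filter, thinning, and leaving out mitochondrial, ribosomal protein and haemoglobin genes, each of the 5 counts of genes stayed within 1.5 times its value, but the share called higher went from 50.9% to 35.4% (Kit in K5+ cells) and from 69.9% to 58.5% (interaction) with upper-quartile factors, which moved the median of all genes by -0.11 and -0.16. With these factors the majority also turned for K5 in Kit- cells, from 44.8% to 54.4% higher, and for Kit in K5- cells, from 47.7% to 53.0%, with the median moved by 0.11 and 0.0592. The share also went from 50.9% to 44.6% for Kit in K5+ cells with DESeq2 size factors. The correlation of the 2 K5 differences was 0.106 with TMM and with DESeq2 size factors.

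For K5 in Kit+ cells the count of 0 became 318 with no filter on low counts, 123 with DESeq2, 54 with a block on library number, 34 with epithelial scaling and 3 without libraries 1 to 4, and was 0 to 4 without any 1 library. For K5 in Kit- cells 2806 became 9452 with epithelial scaling, and 1691, 548 and 1710 without libraries 1 to 4, 5 to 8 and 9 to 12 (1362 to 3157 without 1). For Kit in K5+ cells 112 became 1212 with no filter, 1092 with DESeq2, 58 with limma-voom, 72 with only the 2 groups, 788 with the block, 848 with epithelial scaling, and 8, 1 and 9 without the 3 sets of libraries (4 to 240 without 1). For Kit in K5- cells 3624 became 13157 with epithelial scaling and 851 and 2226 without libraries 5 to 8 and 9 to 12 (2123 to 3754 without 1). The interaction count of 684 became 1960 with no filter, 1434 with DESeq2, 1418 with the block, 6306 with epithelial scaling, and 452, 87 and 343 without the 3 sets (370 to 729 without 1). Fewer libraries were fitted when sets were left out; for the other settings the cause was not tested. Epithelial scaling moved the median of all genes by 0.16, -1.42, -0.65, -2.22 and 1.57 in the 5 comparisons. Of genes then called, only 2.94% and 1.91% were higher for K5 in Kit+ and in Kit- cells. For Kit in K5+ and in K5- cells 1.42% and 0.24% were higher, and for the interaction 98.0%.

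The block on library number gave 4057 genes for K5 in Kit- cells and 4977 for Kit in K5- cells. With thinning as well, the counts were 43 and 3984 for K5 in Kit+ and Kit- cells, 689 and 4894 for Kit in K5+ and K5- cells and 1310 for the interaction, and Krt17 for Kit in K5- cells then lost its call (adjusted p = 0.0692). Beyond the calls and counts printed beside their results, the block changed no other call that the report gives for a gene in a comparison or for a list. Ccnd1, given above only for Kit in K5- cells, passed for Kit in K5+ cells with the block only (log2 1.74 ± 0.27, adjusted p = 0.00559, and 0.0539 without it).

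Of the 52 list calls, 0 were kept with an estimated correlation; the number of calls was 43 with fry and 46 to 64 with other scaling, prior count, block or libraries left out. Signs turned with epithelial scaling for Kit (0.12) and Smgc (0.0432) for K5 in Kit+ cells; for Kit (-0.83), Egfr (-0.20), Kif23 (-0.0583) and Nusap1 (-0.24) for K5 in Kit- cells; for Cdh1 (-0.31), Smgc (-0.65) and Col3a1 (-0.46) for Kit in K5+ cells; and for Cdh1 (-0.28), Etv4 (-0.17), Etv5 (-0.23), Krt17 (-0.52), Ccnd1 (-0.0291), Erbb3 (-0.13), Ube2c (-0.74), Birc5 (-0.83), Rrm2 (-0.22) and Uhrf1 (-0.98) for Kit in K5- cells. For K5 in Kit+ cells, signs of genes that did not pass also turned for Smgc with no filter (0.0049), Trp63 with upper-quartile factors (-0.0140), Kit (0.0789) and Trp63 (-0.0966) without libraries 1 to 4 and Col3a1 (-0.14) without libraries 5 to 8, and for Smgc with limma-voom (-0.0676) for Kit in K5+ cells. Without 1 library, log2 values for K5 in Kit+ cells ranged from -0.22 to 0.13 (Kit), -0.13 to 0.41 (Cdh1), -6.86 to 0.52 (Bpifa2), -2.64 to 2.54 (Smgc) and -0.49 to 0.50 (Trp63), and for Kit in K5+ cells from -0.83 to 7.35 (Bpifa2) and -2.11 to 2.93 (Smgc). Depth limits genes near the floor of 3 counts, and at this spread most 2-fold changes in simulated data were missed.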

Other observations

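Secretory genes differed between libraries of the same population. Bpifa2, a secreted salivary protein, had 4432, 182 and 1.02 CPM in the Kit+ K5- libraries and 370.4, 25.3 and 0.388 CPM in the Kit+ K5+ libraries. Smgc, a submandibular gland protein whose exons overlap Muc19, had 1673, 77.6 and 3.98 CPM in the Kit- K5- libraries and 311, 39.3 and 3.63 CPM in the Kit- K5+ libraries. In each of these 4 populations the higher libraries were numbered 1 to 4 and the lowest 9 to 12.

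A test of this difference between runs of library numbers, chosen after the values had been seen, called 606 genes by edgeR's quasi-likelihood test. Among 20 acinar secretory genes 11 were called, all lower in libraries 9 to 12 than in libraries 1 to 4, with a median log2 difference of -2.26 over the list. Of the luminal duct list 7 of 19 were called, of the dissociation stress list 12 of 19, of the mast cell list 7 of 8 and of the leukocyte and macrophage list 6 of 13, against 0 of 16 mesenchyme and 0 of 24 DNA replication genes. The design gives no group for these runs, and no biological explanation was tested.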
